A study of Mus musculus with 6 samples.

How the data were processed

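MicroRNA was measured in mouse 3T3-L1 cells, a fibroblast line that turns into fat cells under a hormone cocktail. The 6 samples, 4 untreated controls and 2 exposed to interleukin-6 (IL-6) at 1 ng/ml, were taken on day 8 of differentiation. Groups and replicate numbers came from the sample titles. Per the labels' protocols, 100 ng of total RNA with an RNA integrity number between 9.5 and 10.0 was labelled with Cy3 together with spike-in RNAs and hybridised to 1-colour Agilent mouse miRNA arrays. Per the file headers and the submitters' processing notes, spots were read with Agilent Feature Extraction 10.10.1.1.

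The scanner values used here are intensity values which, per the file headers, had a spatially fitted background subtracted and no surrogate put in for dim spots, so that they can be negative. The deposited spot flags, a unit of their own, mark spots that are well above background, uneven, outlying within their probe, or saturated. The raw mean and local background intensity columns, also deposited by the authors, served only one alternative. The deposited series table holds linear intensity values that equalled the scanner's total signal per probe exactly on all 6 arrays (largest difference 0). It was neither log-transformed nor centred, and a 1-colour array leaves no direction open. Its column medians were 0.0937, 0.104, 0.0777 and 0.0781 for controls 1 to 4 and 0.0727 and 0.117 for IL-6 1 and 2. A normalization that the authors may have applied later is not given in the sources used here.

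Each array held 49880 spots for 1247 mouse miRNAs and 3105 probes, and 2164 control spots, which were left out. Spots marked as uneven or as outliers were left out, the remaining spots of a probe were averaged, and a probe counted as detected where a share of at least 0.5 of its spots was well above background. Because most probes were not detected, each array was scaled by the 75th percentile of its 502 probes detected on all arrays, and multiplied by the mean of these percentiles. Probes of a miRNA were averaged on the linear scale. Values below 6.25, the highest of the lowest detected signals per array, were then set to that floor before log2 was taken, which understates changes of dim miRNAs. Of the 254 tested miRNAs with more than 1 detected probe, 25 had probes whose differences went both ways. The 299 miRNAs detected on all 4 control arrays or on both IL-6 arrays were tested. No spot was saturated.

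The comparison of IL-6 with control used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) over all 6 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors beside a log2 difference of a miRNA are limma's standard errors. Errors beside a within-column median are standard errors of a median over the miRNAs of a set, since each column holds 1 array per group, and carry no error between samples. A miRNA not well above background on any control array has only a bound there, and its fold is written as "at least". Where no control array sat at the floor, the fold is given as an estimate. The bound sets the IL-6 mean against, per control array, the higher of the floor and the miRNA's own signal, and is the lower of the fold of the miRNA and that of its lowest detected probe. It holds for the main processing and not for every alternative setting. It is a bound on the estimate and leaves out the spread between arrays, so it does not exclude a smaller change. Lists of miRNAs were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. 17 lists with 319 entries were written from general knowledge before the data were examined, as were the main tests, the first set of alternatives and the naming rule. Of the 94 tested members, 45 were in more than 1 list. Of the entries, 303 were on the array, and 14 lists had at least 3 tested members. Numbers of detected miRNAs were compared with an exact two-sided permutation test over all 15 splits of 6 arrays into 4 and 2.

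The text names, in each direction, up to 12 miRNAs past the threshold with separate groups, ordered by size. Where fewer than 8 existed, those with the smallest unadjusted p made up the 8. It also names, in each list, up to 6 members past the threshold and the 2 tested members with the highest signal, the 5 miRNAs with the highest signal, and up to 5 detected on every array of one group and none of the other. Other miRNAs are named as chosen after their values were seen or to complete a list. The checks on repeat-like probes, and those on slide columns other than the within-column medians of the Sfmbt2 cluster list, were also chosen then. The fit was tested on simulated data, with 20 sets of 6 arrays drawn from the means and spreads of the 299 tested miRNAs. It called 72.0% of miRNAs changed 1.5-fold and 93.5% of those changed 2-fold, all in the right direction, and 0.676% of unchanged ones. Each set held 10 changed miRNAs at each of 1.25-, 1.5-, 2- and 3-fold, which eases the adjusted threshold. No floor or detection filter was applied to the simulated values, so these rates need not hold for the real arrays. In the same simulation, camera called a list shifted 1.5-fold in 100% of sets and none of 280 unchanged lists. Those arrays held no slide effect, and their miRNAs were drawn independently of one another. They therefore do not show how camera fares where list members move together. The estimated correlation of the Sfmbt2 cluster list was 0.157.

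Positions are those the array files list for a probe, printed only where they fall inside the gene of that miRNA in the RefSeq table of GRCm38.p6. The files' headers name mm9 while their probe positions mix builds, so 275 of 299 tested miRNAs could be placed. The table gives gene bounds and not exons. The first block of each file gives the array's place on the slide. All 6 arrays lay on 1 slide scanned once, with the controls in row 1, columns 1 to 4, and IL-6 1 and 2 in row 2, columns 3 and 4. Columns 3 and 4 each held 1 array per group, so values are given within these columns and with column as a block. Row cannot be told apart from treatment. Alternatives covered the scaling, background correction, probe summary, detection filter, outlier spots, series table, variance model, replicate block, each array left out, thresholds, and the list correlation. Those on slide columns, spike-in scaling and flat miRNAs were added after seeing the data. The figures were drawn with matplotlib 3.10.9.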

Results

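The series profiled miRNA in mouse 3T3-L1 adipocytes on day 8 of differentiation, and asked which miRNAs differed when IL-6, an inflammatory cytokine, was present from the induction of differentiation at 1 ng/ml. Medium was renewed every 24 h. Intensities came from 4 control arrays and 2 IL-6 arrays. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

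Detected miRNAs numbered 284, 294, 268 and 287 on control arrays 1 to 4 and 313 and 300 on IL-6 arrays 1 and 2. The means were 283 ± 11.0 (SD, n = 4) and 307 ± 9.19 (SD, n = 2), a difference of 23.3 with an exact two-sided permutation p of 0.0667, the smallest that 15 splits allow (0.133 after Benjamini-Hochberg adjustment over 2 counts). By the scanner software's own detection call the difference was 25.8, with an exact permutation p of 0.2. IL-6 minus control was 45 miRNAs within slide column 3 and 13 within column 4. The 75th percentile used for scaling was 347, 396, 248 and 343 intensity units on the controls and 440 and 369 on the IL-6 arrays. A hybridisation spike-in lay between 4.57 and 4.64 (log10) on all arrays. The labelling spike-in metric lay between 1.72 and 2.00 (log10), outside the scanner software's range on all 6 arrays.

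miR-5117-5p was the single miRNA that passed the test, and it rose with IL-6. It was well above background on both IL-6 arrays and on no control array. Under the main processing its estimate was therefore at least 2.04-fold higher (log2 difference 1.03 ± 0.09 SE, limma adjusted p = 0.0068). The levels were 3.77 ± 0.09 (log2, SD, n = 2) with IL-6 and 2.74 ± 0.11 (SD, n = 4) in controls. As bounds, since no control array detected it, the difference was at least 1.04 within slide column 3 and at least 0.84 within column 4, and 1 of its 2 probes was detected. Control arrays 1 and 2 sat at the floor, which narrows the control spread behind the call. Over the alternative settings the difference ran from -0.0035, with normexp background correction, to 1.54, and it was 0.41 with the brightest probe. The 3p arm of the same hairpin differed by -0.16. No miRNA passed in the other direction (limma), where the smallest adjusted p was 0.0795. At an unadjusted p under 0.05, limma gave 32 miRNAs higher and 36 lower with IL-6, where chance alone gives 14.95 in all on average. Counts can spread widely around that mean when miRNAs move together, and the other splits of the 6 arrays gave between 0 and 69. The balance of higher and lower depended on the scaling, with 50 higher and 0 lower without scaling, 47 and 0 with spike-in scaling, and 31 and 69 with scaling over all mouse probes.

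The next smallest p-values in the higher direction belonged to 7 miRNAs that did not pass (limma adjusted p between 0.0724 and 0.0845), with both IL-6 arrays above all 4 controls for each. miR-574-5p, rich in GU repeats, measured 7.14 ± 0.06 (log2, SD, n = 2) against 6.37 ± 0.16 (SD, n = 4), a difference of 0.77 ± 0.12 SE. Its probe is listed at chromosome 5, 64970334 to 64970350 (GRCm38), within the bounds of Fam114a1 and Tlr6. miR-466i-5p, another GU-repeat miRNA, differed by 0.94 ± 0.15 SE from 7.34 ± 0.22 in controls. Its probe is listed at chromosome 13, 17747527 to 17747544, within Cdk13. miR-1187 differed by 0.95 ± 0.18 SE, miR-1196-5p by 1.34 ± 0.25 SE and miR-706 by 1.05 ± 0.21 SE. miR-681 and miR-6354 were above background on no control array and were at least 1.62-fold and at least 1.20-fold higher. The former sat at the floor on 3 control arrays and miR-6354 on all 4, which narrows the control spread behind their p-values. For each, 1 probe was detected. Within slide columns 3 and 4 the differences were 1.00 and 0.65 for miR-574-5p, 1.28 and 0.75 for miR-466i-5p, 1.41 and 0.70 for miR-1187, and 1.93 and 0.98 for miR-1196-5p.

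In the lower direction, all 8 named miRNAs had both IL-6 arrays below all 4 controls, and none passed (limma adjusted p between 0.0795 and 0.106). miR-143-3p, which promotes adipocyte differentiation in culture, measured 9.09 ± 0.07 (log2, SD, n = 2) with IL-6 and 9.48 ± 0.11 (SD, n = 4) in controls, a difference of -0.39 ± 0.08 SE. Its probe is listed at chromosome 18, 61649240 to 61649255. miR-155-5p, a miRNA of inflammatory signalling that restrains adipogenesis, differed by -0.35 ± 0.08 SE from 7.27 ± 0.08 in controls. miR-31-5p differed by -0.30 ± 0.06 SE and miR-183-3p by -0.49 ± 0.11 SE. The differences were -0.33 for miR-5097, -0.29 for miR-378c, -0.27 for miR-30a-3p and -0.24 for miR-212-3p, each 1.18-fold to 1.26-fold lower. Within slide columns 3 and 4, miR-143-3p differed by -0.48 and -0.36, miR-31-5p by -0.30 and -0.31, and miR-155-5p by -0.18 and -0.38.

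The call rested on few arrays. With slide column as a block, no miRNA passed (limma, 34 higher and 16 lower at an unadjusted p under 0.05), and miR-5117-5p had a difference of 0.94 with an adjusted p of 0.177. This block left almost no arrays over for estimating the spread, so failing the adjusted threshold was likely in advance. The standard error of miR-5117-5p was 0.088, against 0.086 without the block, so the lost call says little about slide columns. Over the alternatives, the limma adjusted p of miR-5117-5p ran from 0.000156 to 0.848. Without control array 4, 23 miRNAs passed as higher and 8 as lower, a set that included miR-574-5p (0.79, adjusted p = 0.0398), miR-466i-5p (0.98, adjusted p = 0.0398), miR-143-3p (-0.42, adjusted p = 0.0437) and miR-31-5p (-0.32, adjusted p = 0.0437). Without control array 3 none passed (limma, 26 higher and 70 lower unadjusted), and 5 and 4 passed as higher without IL-6 array 1 and without IL-6 array 2. With quantile scaling 1 miRNA passed in each direction, the lower one miR-17-3p (-0.39), named after its value was seen.

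**Figure D1:**
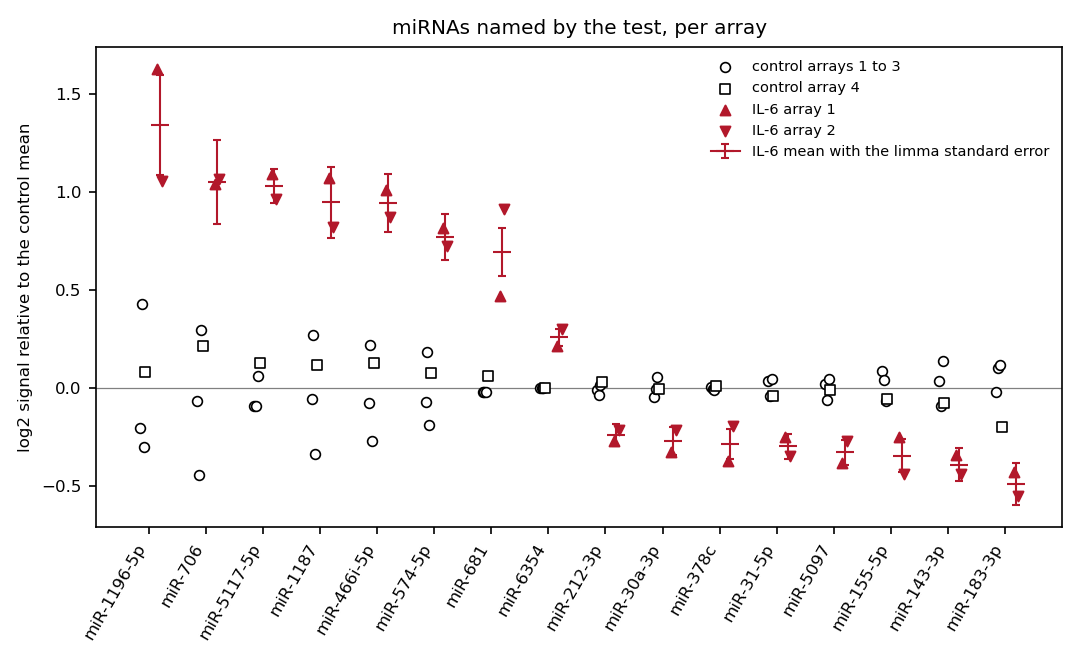
Log2 signal of each array minus the control mean for the 16 miRNAs chosen by p-value, with control arrays as open symbols, IL-6 arrays as filled triangles and the IL-6 mean with its limma standard error. Both IL-6 arrays lie outside all 4 control arrays for each miRNA, from 1.34 for miR-1196-5p to -0.49 for miR-183-3p, and only miR-5117-5p passed the adjusted threshold.

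One of 14 tested lists, the Sfmbt2 cluster list, was shifted higher with IL-6 (median log2 difference 0.89, camera adjusted p = 0.0044). With an estimated correlation the shift did not pass (p = 0.0686, adjusted p = 0.775). This list holds miR-297, miR-466, miR-467 and miR-669 names, most of them from a large repeat-rich miRNA cluster within the Sfmbt2 gene. Of its 10 tested members, none passed over all miRNAs tested, and 7 higher and 0 lower passed when adjusted over the list alone. miR-466f-3p differed by 1.24, miR-466i-3p by 1.03, miR-467f by 0.92, miR-669c-3p by 0.91, miR-466h-3p by 0.88 and miR-669n by 0.50, beside miR-466i-5p above; those not named by rule are given to complete the list. miR-669f-3p differed by 0.03, miR-467a-3p by -0.13 and miR-467b-5p by -0.19. The median was 0.72 within slide column 3, 0.43 within column 4 and 0.60 with column as a block (camera adjusted p = 0.0139). Without IL-6 array 1 the list did not pass (median 0.80, camera adjusted p = 0.067). Over all alternatives the median ran from -0.02 to 1.04 and the adjusted p from 4.2e-05 to 0.775, and the low end came from normexp background correction, under which 36 of the list's 60 values sat at the floor.

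By the file positions, 6 of the 10 members lay within Sfmbt2 on chromosome 2, such as miR-466h-3p at 10514946 to 10514958 and miR-669c-3p at 10509363 to 10509380. The other 4 lay elsewhere, with both arms of miR-466i within Cdk13 on chromosome 13, miR-467f within Fxr2 on chromosome 11 and miR-669n within Slc30a7 on chromosome 3. Of the members inside the gene, 3 of 6 were higher at an unadjusted p under 0.05, with a median of 0.46, and of those outside, 4 of 4 were, with a median of 0.93. With miR-669p-3p (0.86), which lies inside the gene and not in the list and was named after its value was seen, 4 of 7 inside were higher, with a median of 0.86.

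None of the other lists passed. For the 13 tested miRNAs tied to brown and beige fat the median was -0.18 (camera adjusted p = 0.0574), with 10 below 0 and 3 above. Among them miR-193a-3p differed by -0.27 ± 0.09 SE and miR-365-3p by -0.18 ± 0.11 SE. The clusters of miR-23, miR-24 and miR-27 had a median of -0.16 over 6 members, all below 0 (camera adjusted p = 0.0638), with miR-23a-3p at -0.16 and miR-24-3p at -0.15. The 22 pro-adipogenic miRNAs had a median of -0.11 (camera adjusted p = 0.0849), with 18 below 0, among them miR-21a-5p at -0.15 and miR-103-3p at -0.11. Over these lists no member passed, whether over all miRNAs or adjusted over the list alone. The medians within slide columns 3 and 4 were -0.18 and -0.04 for brown and beige fat, -0.29 and -0.04 for the miR-23 to miR-27 clusters, and -0.11 and -0.04 for the pro-adipogenic list. With column as a block the medians were -0.10, -0.17 and -0.07. Without control array 4 all 3 lists passed (camera adjusted p = 0.00744 for brown and beige fat, 0.0258 for the clusters and 0.0225 for the pro-adipogenic list). They also passed with the file's total signal per miRNA (camera adjusted p = 0.0203 for each), which moved the median of all tested miRNAs by -0.094. All 3 passed with the series table (camera adjusted p = 0.0235, 0.0235 and 0.0401), and the first 2 with no detection filter (0.0383 and 0.0497). Leaving out slide column 4 leaves 1 IL-6 array, so p-values of that setting are not given. With an estimated correlation over all arrays none passed (adjusted p = 0.775 for each, the highest of their alternatives).

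The 21 miRNAs of insulin signalling and glucose uptake had a median of -0.06 (camera adjusted p = 0.13), with miR-21a-5p as above and let-7a-5p at -0.03. That median was -0.16 without control array 3, -0.10 without control array 4, -0.11 without IL-6 array 1 and -0.01 without IL-6 array 2, and the list passed with the file's total signal per miRNA (-0.17, adjusted p = 0.0203, between that and 0.775 over its alternatives). The 16 of inflammation and STAT3 or NF-kB signalling, of which STAT3 acts downstream of the IL-6 receptor, had a median of -0.0024 (camera adjusted p = 0.587), with miR-21a-5p as above and miR-125b-5p at -0.10. Its median ran from -0.11 to 0.02 over the alternatives. The 20 anti-adipogenic miRNAs had a median of -0.02 (camera adjusted p = 0.638), with 9 above 0 and 11 below and medians of 0.06 and 0.05 within slide columns 3 and 4 and 0.07 with column as a block. Over the alternatives the median ran from -0.13, with scaling over all mouse probes, to 0.07. The members with the highest signal were let-7a-5p at -0.03 and let-7f-5p at -0.05. Over all miRNAs none passed, and 1 higher and 2 lower passed when adjusted over the list alone, miR-709, miR-31-5p and miR-155-5p, the first named after its value was seen. The let-7 family had a median of 0.02 (camera adjusted p = 0.638), the miR-17 cluster with its paralogs 0.0039 (camera adjusted p = 0.638, with a mean of -0.04 and a test statistic below 0), with miR-19b-3p at 0.01 and miR-106b-5p at 0.03, and the miR-29 family -0.05 (camera adjusted p = 0.694), with miR-29a-3p at -0.06 and miR-29b-3p at -0.05. The miR-30 family had a median of -0.09 (camera adjusted p = 0.489), with miR-30a-5p at -0.20 and miR-30b-5p at -0.09, and -0.15 without control array 3, -0.18 without control array 4 and -0.16 without IL-6 array 1. Scaling over all mouse probes, which moved the median of all tested miRNAs by -0.11, put the let-7 and miR-17 cluster medians at -0.09 and -0.11.

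The 16 mesenchymal and fibrosis miRNAs had a median of -0.06 (camera adjusted p = 0.241), with miR-199a-3p at -0.05, and 2 lower passed when adjusted over the list alone, miR-143-3p and miR-31-5p. That median was -0.11 without control array 3 or without IL-6 array 1 and -0.0027 without IL-6 array 2, and the list passed with the file's total signal per miRNA (-0.17, adjusted p = 0.0216, between that and 0.788 over its alternatives). Of 60 Dlk1-Dio3 miRNAs on the array, 5 were tested, with a median of 0.02, a mean of 0.32 and a camera adjusted p of 0.694. Among these, miR-494-3p differed by 1.27 ± 0.56 SE and miR-370-3p by 0.63 ± 0.30 SE, with overlapping groups. Over the alternatives the median of the Dlk1-Dio3 list ran from -0.04 to 0.63. Of the lists for other cell types, 4 epithelial miRNAs were tested (median -0.25, camera adjusted p = 0.329), among them miR-96-5p at -0.40 ± 0.14 SE and miR-182-5p at -0.20 ± 0.07 SE. Of the neural, endothelial and liver list 1 was tested, miR-128-3p at 0.10, and 0 of the 7 muscle and 0 of the 6 blood cell miRNAs on the array were.

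**Figure D2:**
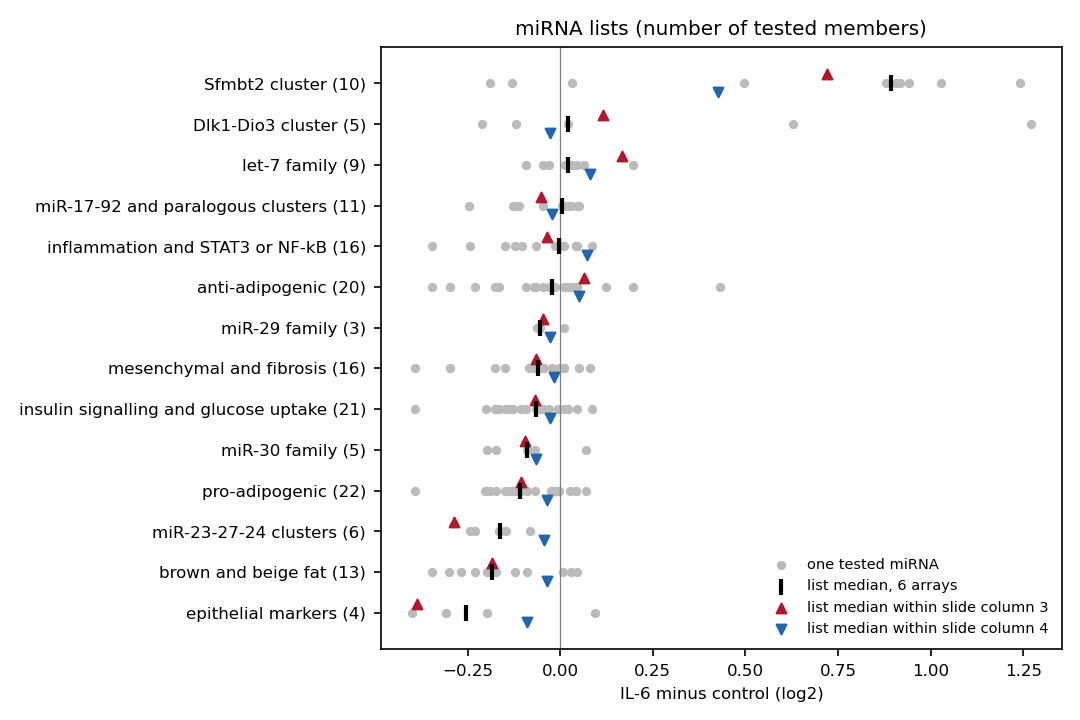
IL-6 minus control (log2) for the 14 tested lists, with each tested miRNA as a grey point, the median over 6 arrays as a bar, and the medians within slide columns 3 and 4 as triangles. The Sfmbt2 cluster list lies apart at a median of 0.89, with 0.72 and 0.43 within the columns, and the brown and beige fat list lies at -0.18, with -0.18 and -0.04.

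The 5 miRNAs with the highest signal did not pass. These were miR-6366 (-0.20 ± 0.09 SE), miR-3963 (-0.19 ± 0.11 SE), miR-5100 (-0.24 ± 0.08 SE), miR-3968 (-0.26 ± 0.07 SE) and miR-5126 (-0.06 ± 0.11 SE). On both IL-6 arrays and no control array, 10 miRNAs were detected, and none the other way. These counts rest on unlike requirements, since a dim miRNA is less readily detected on all 4 controls than on both IL-6 arrays. The IL-6 arrays also detected more miRNAs on average (307 against 283), so the contrast cannot be read by itself. Of the 10, beside miR-5117-5p, those with the highest signal were miR-6418-5p, miR-6394, miR-3572-5p and miR-3067-3p (limma adjusted p between 0.0845 and 0.360). The first was at least 1.58-fold and miR-6394 at least 1.45-fold higher. Estimates were 1.34-fold for miR-3572-5p (log2 difference 0.42 ± 0.17 SE) and 1.16-fold for miR-3067-3p (0.21 ± 0.13 SE). For miR-3572-5p and miR-3067-3p the groups overlapped, with control array 4 above IL-6 array 1. No control array sat at the floor for either, so their folds are no bounds, and no rise at all stays possible. Across all tested miRNAs, the IL-6 arrays lay outside the control range for 104 of 299, 39 higher and 65 lower, where chance gives 13.3% on average. Shares can spread widely around that mean when miRNAs move together.

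Both arms were tested for 34 hairpins. Across hairpins, which are not independent replicates, the differences of the 5p and 3p arms correlated with Pearson's r = 0.48 (permutation p = 0.0126, Benjamini-Hochberg 0.0253 over 2 relations) and Spearman's rho = 0.36 (permutation p = 0.0369, Benjamini-Hochberg 0.0369). Without miR-3096b and miR-5117, the hairpins farthest from the median of the 5p arm, r was 0.67. Without miR-466i, the hairpin farthest from the medians of both arms, r was 0.25, so the size of the correlation rests on it. Both arms were below 0 in 17 hairpins, such as miR-31 (-0.30 and -0.35), above 0 in 5, such as miR-466i (0.94 and 1.03), and opposite in 12. Among those above 0, miR-574 had 0.77 for its 5p and 0.06 for its 3p arm. Among the 12 opposite, miR-5117 had 1.03 for its 5p and -0.16 for its 3p arm.

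The 2 slide columns that hold both groups gave related differences. IL-6 minus control within column 3 and within column 4 correlated at r = 0.64 across the 299 tested miRNAs, which are not replicates, with the same sign in 74.9%.

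**Figure D3:**
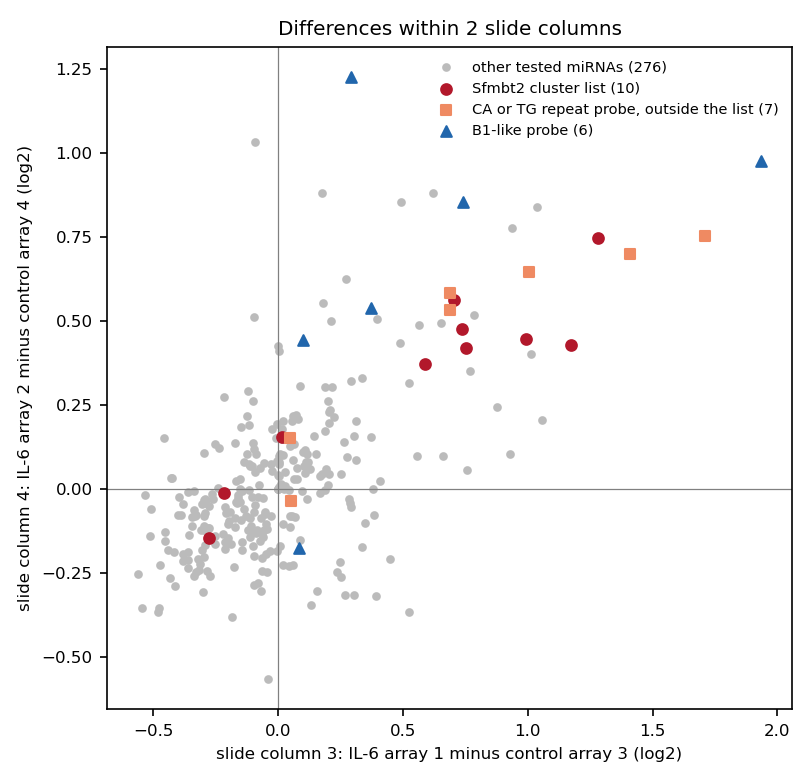
IL-6 minus control (log2) within slide column 3 (x axis) and within column 4 (y axis), 1 point per tested miRNA. Members of the Sfmbt2 cluster list, other miRNAs with CA or TG repeat probes and miRNAs with probes like the B1 repeat lie mostly above 0 in both columns, as with miR-466i-5p at 1.28 and 0.75.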

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

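The tests of the shared departure of control array 4 and IL-6 array 2 were chosen after the result was seen. Of 56 groups of 4 control arrays that were checked, chance would set apart an array in about 2.80. Control array 4 stood apart from the other 3 for miR-199a-3p (11.35 log2), miR-23a-3p (11.16), miR-365-3p (9.63) and miR-370-3p (4.75), and for a hybridisation spike-in (4.57, log10). For miR-681 (2.73) the other 3 sat at the floor and none of the 4 detected it, so that this value says nothing about the array. Control array 3 stood apart for miR-106b-5p (7.89). Among control spots outside the measurement, a bright corner marker was 0.40 higher (log2) on the IL-6 arrays, with both above all 4 controls.

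Control array 4 moved away from the other controls in step with IL-6 array 2, which shared its slide column. IL-6 array 2 minus IL-6 array 1 correlated at r = 0.57 across tested miRNAs with control 4 minus control 3, and the pair was high for miR-494-3p, miR-5121 and miR-6243 (control 4 minus control 3 of 1.33, 2.19 and 1.14). The yield of labelling stays open. The labelling spike-in of IL-6 array 2 exceeded that of IL-6 array 1 by 0.0389 (log10) as measured and by 0.115 after scaling. As measured, control 4 exceeded the highest of controls 1 to 3 by 0.165, while IL-6 array 2 exceeded it by 0.0641. After scaling, IL-6 array 2 lay below control 3 for the probes of 1 labelling spike-in (6.86 against 6.91 and 7.48 against 7.59, log2). The probes of the other gave 3.74 against 3.89 and 4.34 against 4.33. A difference between slide columns stays open too, as does any handling that the same arrays shared. No biological explanation was tested, because the design gives no group that joins these arrays.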

How the results depend on the processing

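The 47 named miRNAs were tested under 23 alternative settings (39 of them) or 22, and 36 of the 47 did not change sign in any. A sign counted as changed only if an estimate exceeded its own standard error in the main or the other setting. Without scaling and with spike-in scaling, signs were taken after removing the shift in the median of all tested miRNAs. The count of 36 does not cover signs before that removal. Signal over background limits the dim miRNAs, since 49 of 1794 tested values sat at the floor. The alternatives on slide columns, on spike-in scaling and on miRNAs at the floor were chosen after seeing the data. Where not stated otherwise, the cause of a change was not tested. Without scaling 34 miRNAs were higher, and with spike-in scaling 31, because all tested miRNAs then moved by a median of 0.28 and 0.30, relative to which the lists and named miRNAs are given. Scaling over all mouse probes gave 2 higher, and as it moved the median of all tested miRNAs by -0.11, let-7 stood at -0.090, the miR-17 cluster at -0.11, miR-128-3p at -0.0098 and miR-19b-3p at -0.10. Quantile normalization gave 1 lower, with miR-128-3p at -0.0043. Normexp correction, with a floor of 89.1 by construction, gave 0 higher (6 at an unadjusted p under 0.05, limma) and 0 lists. The Sfmbt2 cluster list then stood at -0.023, the miR-17 cluster at -0.10, miR-128-3p at -0.045, miR-3067-3p at -0.0080, miR-3572-5p at -0.0089, miR-370-3p at -0.0046, miR-5117-5p at -0.0035, miR-6394 at -0.0076, miR-6418-5p at -0.0011 and miR-706 at -0.0036. The brightest probe gave 2 higher, with the miR-17 cluster at -0.045. The file's total signal per miRNA gave 12 higher, 26 lower and 6 lists (beside Sfmbt2, brown and beige fat, the miR-23 to miR-27 clusters, pro-adipogenic, insulin and mesenchymal), with let-7 at -0.087, the miR-17 cluster at -0.10, miR-106b-5p at -0.078, miR-128-3p at -0.0060 and miR-19b-3p at -0.10. Requiring detection on all 6 arrays gave 0 higher (21 unadjusted, limma), since miR-5117-5p is then not tested. No filter gave 3 lists, the first 2 of these and Sfmbt2, and the series table gave 0 higher (29 unadjusted, limma) and 4 lists, adding the pro-adipogenic one. An unadjusted p under 0.05 with at least 1.5-fold gave 19 higher. With an estimated correlation 0 lists passed, the Sfmbt2 cluster list at 0.89. Deviations from the group means correlated at r = 0.0582 for control 1 with IL-6 1 and at -0.338 for control 2 with IL-6 2, so the numbers are not shown to pair samples, and a replicate block gave 0 higher (36 higher unadjusted, limma) and 2 lists, the other being brown and beige fat (-0.19, camera adjusted p = 0.0144), with let-7 at -0.088. Slide column as a block gave 0 higher, with the anti-adipogenic list at 0.074 and let-7a-5p at 0.10, and columns 3 and 4 alone gave 0 (21 unadjusted, limma), with that list at 0.056. Either block, by replicate or by column, left almost no arrays over for estimating the spread, so a count of 0 was likely in advance. Without column 4, 7 were higher and the same 4 lists as with the series table passed, with the miR-29 family at 0.018. Leaving the 2 miRNAs at the floor on all arrays out of the variance fit gave 3 higher, miR-5117-5p, miR-466i-5p and miR-574-5p. Leaving out 1 array at a time gave between 0 and 23 higher, between 0 and 8 lower and between 0 and 4 lists, where a lone IL-6 array is assumed to vary like the others. The Sfmbt2 cluster list then lay between 0.77 and 0.98, let-7 between -0.10 and 0.070, the miR-17 cluster between -0.11 and 0.0067, the miR-29 family between -0.11 and 0.0050, miR-19b-3p between -0.077 and 0.035 and miR-128-3p between -0.029 and 0.23.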

Other observations

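All tests in this part except those of the slide columns and of signal level for the Sfmbt2 cluster list were chosen after the result was seen. The miR-378 family, chosen after its values were seen, lay below 0 in every tested member without passing. miR-378a-3p and miR-378a-5p, from a hairpin within Ppargc1b, a coactivator gene of mitochondrial metabolism, differed by -0.19 ± 0.07 SE and -0.20 ± 0.07 SE. miR-378b, miR-378c and miR-378d differed by -0.24, -0.29 and -0.23, though near-identical sequences may be read by each other's probes. With the file's total signal per miRNA, which moved the median of all tested miRNAs by -0.094, miR-378a-3p at -0.30, miR-378b at -0.34, miR-378c at -0.39 and miR-378d at -0.34 passed (adjusted p between 0.0196 and 0.047, and up to 0.989 over the alternatives for miR-378c). Of other miRNAs with large differences, miR-3473b at 0.96 ± 0.49 SE and miR-3470a at 0.89 ± 0.23 SE did not pass either.

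The Sfmbt2 cluster list had a median difference of 0.89, which passed with the preset correlation (camera adjusted p = 0.0044) and neither with an estimated one (adjusted p = 0.775) nor without IL-6 array 1 (camera adjusted p = 0.067). The tables argue against a trend along the slide columns, as the lower of the 2 within-column medians was 0.43 ± 0.11 SE over its members. Of 10000 random lists of like level, 0% reached the list's median. Their members were drawn singly, while those of the list may move together (estimated correlation 0.157). Under normexp background correction the median was -0.02, with 36 of the list's 60 values at the floor. Low signal therefore stays open. RNA with GU repeats in general stays open and would reach only the 2 of 10 members with CACACA in a probe, against 7 with TGTGTG; the 4 tested miRNAs outside the list with CACACA had a median of 0.86 (miR-3082-5p 1.09, miR-1187 0.95, miR-574-5p 0.77, let-7b-5p 0.03) and the 3 with TGTGTG 0.86 (miR-466q 0.97, miR-669p-3p 0.86, miR-574-3p 0.06), sets formed after miR-574-5p and miR-1187 were seen, so that these medians decide nothing. Slide row cannot be told apart from treatment, because 0 control arrays lay in the row of the IL-6 arrays. IL-6 itself stays open as the biological explanation, untested against the row.

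miRNAs with a probe that matched the B1 repeat, a short interspersed element common in mouse transcripts, with at most 1 mismatch had a median difference of 0.66 over 6. These were miR-1196-5p (1.34), miR-706 (1.05), miR-3470a (0.89), miR-709 (0.43), miR-5118 (0.27) and miR-2861 (-0.05). The probe CCGCCCGCCG of the last is short, and miR-5118 lay at the floor on all controls. Low signal stays open, because the set was formed after its highest members were seen and the share of random lists of like level that reached its median, 0.110% of 10000, then decides nothing. A trend along the slide columns stays open too, with a lower within-column median of 0.33 ± 0.36 SE over its members. Of the 6, 3 lay under 0.3 in column 3. Fragments of repeat-rich transcripts may add to the signal, a hypothesis that these values do not decide. The same check with the B2 repeat matched miR-3473b (0.96), miR-671-5p (0.13) and miR-5128 (0.06), with 0 higher at an unadjusted p under 0.05 (limma). The 274 tested miRNAs without any of these repeat matches had 15 higher and 36 lower at that level, with a median of -0.04. This split, too, was formed after values were seen.

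The real split of the 6 arrays gave 1 miRNA past the threshold and the other 14 gave at most 0. Thus 1 of 15 splits reached it. The tested miRNAs had been chosen by detection within the real groups, and the miRNA that passed was detected on no control array. It was therefore tested only through its detection on the IL-6 arrays, which favours the real split. For this reason the share does not decide whether the call arose by chance. 15 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the split that joins control 4 and IL-6 2, the arrays of slide column 4, gave 69 miRNAs against 68 for the real one, which points to a structure of the samples beside the treatment. With slide column as a block, limma gave 0 miRNAs past the threshold, and 34 higher and 16 lower at an unadjusted p under 0.05. As that block left almost no arrays over for estimating the spread, the count of 0 decides nothing.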
